A study of Homo sapiens with 4 samples.

How the data were processed

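Poly(A)-selected TruSeq RNA libraries of 22Rv1 cells were sequenced as paired-end reads, per the labels' protocols, with 2 control and 2 CD276 knockout libraries; both groups carry the replicate numbers 1 and 3. The authors deposited 1 table of raw counts per gene for the 4 libraries, with values that are whole numbers and column totals that differ. Per the submitters' processing notes, Trimmomatic 0.36, STAR 2.5.2b and featureCounts from Subread 1.5.2 were used with the GRCh38 build. The strand setting, the treatment of multi-mapping reads and the annotation release are not given in the sources used here. Where counting did not use strand, reads of a gene and of an antisense partner cannot be told apart, and where multi-mapping reads were dropped or shared, genes with near-identical copies are under- or over-counted.

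The table had 57500 rows. The 486 rows without a gene name, holding 0.0191% to 0.0290% of the counts of a library, were left out of library sizes and tests. A further 27 rows have names that look like dates, as spreadsheets make of some gene symbols; they stayed in the tests and are not named. 144 names occurred on more than 1 row (1663 rows). Gene type, position, exonic overlap, GC content and transcript length came from GENCODE 29 on GRCh38 for the 54750 of 55351 unique names found there. Exonic overlap is given below for some named genes only, and a gene named without it may share exons too. None was available for SOD2 and DIABLO. Positions are 1-based.

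Library sizes were the sums over named rows. Genes were filtered with filterByExpr, scaled by trimmed mean of M-values (TMM factors 0.962, 0.965, 1.07 and 1.00 for control replicates 1 and 3 and knockout replicates 1 and 3), and tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust=TRUE and glmQLFTest, group as the only term, 2 residual degrees of freedom). The p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. The biological coefficient of variation was 0.158.

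Before the data were examined, 38 gene lists with 987 genes were fixed from general knowledge, not from these samples; 984 genes were matched to the table, 50 of them by an older symbol. Each list was described by the number of members that changed, over all genes and adjusted over the list alone. The 36 lists with at least 5 tested genes were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, and the p-values adjusted over the lists. The groups compared, the tests and the rule for named genes were also fixed then. The rule names CD276, the 10 genes with the largest rise and the 10 with the largest fall among changed genes with at least 5 CPM in the higher group and both knockouts on the same side of both controls, the 3 members of each list with the smallest p, and a few further genes, among them DNMT1 and RB1; some genes the rule names are not reported here. Genes named outside it are marked as chosen after their values were seen.

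The scripts were tested on simulated counts drawn from the real means and library sizes of this comparison. With 200 changed genes among 17570 to 17593 tested, the fit recovered 11% of those changed 1.5-fold, 62% of those changed 2-fold and 96% of those changed 4-fold. False calls numbered 2, 1 and 7. Changes well under 2-fold can thus go undetected. The simulation had far fewer changed genes than the 4111 called in the data. It also gave both groups the same spread, while the knockouts differed more from each other than the controls did. Its recovery and false call rates therefore need not hold for the data. In a simulation of 17595 genes the raised list was called and 0 of 20 unchanged lists were. Its genes were drawn independently of each other. In the data, camera's estimated correlation between members was 0.73 for hypoxia and glycolysis, 0.53 for mitochondrial transcripts and 0.13 for p53 targets. The list result therefore need not hold for the data. In a simulation of 17502 unchanged genes with a GC trend, 5132 genes were called without and 0 with the GC and length offsets.

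The alternatives fixed beforehand were edgeR's RLE scaling, upper quartile scaling, library totals alone, no filter on low counts, a filter of at least 50 counts in every library of 1 group, DESeq2 1.42.0, limma voom, robust=FALSE, the replicate number as a block, leaving out each library in turn, camera with an estimated correlation, fry, lists without shared members, an adjusted p under 0.01, and a test against a fold change of 1.2. A fit to nuclear protein-coding genes alone and a fit with offsets for GC content and transcript length within each library were added after seeing the data. With 1 library left out of a group, the remaining library of that group is assumed to vary like the other group, and 1 residual degree of freedom is left. No label gives a batch, date or lane, and 0 columns of per-sample values were left unused.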

Results

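Poly(A)-selected RNA from 22Rv1 cells, a human prostate cancer line, was sequenced in 4 libraries. The labels put 2 libraries in a control group, with a wild-type genotype and sgGFP in the library names, and 2 in a CD276 knockout group, with sgCD276 in the library names. CD276 encodes B7-H3, a cell surface protein of the B7 immune checkpoint family. The series is about targeting DNA methylation, alone or with B7-H3, in prostate cancers that lost RB1 or turned neuroendocrine, and the comparison asks how the transcriptome of this line differs once CD276 is knocked out. The deposited gene counts summed to 23206271 and 20079050 in control replicates 1 and 3 and to 24437926 and 25802417 in knockout replicates 1 and 3, so that 1 CPM (counts scaled to a total of 1e6) stood for 20.1 to 25.8 counts. Levels are given as mean ± SD of normalized CPM (n = 2 libraries per group) and differences as log2 fold changes of knockout over control ± SE. A gene is described as changed where edgeR's quasi-likelihood test gave a Benjamini-Hochberg adjusted p under 0.05. The series design calls the replicates biological but does not say that they came from separate cultures, so p-values measure the spread between these libraries.

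The targeted gene itself fell by about 2-fold in both knockout libraries. CD276 (chromosome 15, 73683966 to 73714518, plus strand, GRCh38), which is protein-coding and shares no annotated exon with another gene, had 1058 and 1054 counts in the controls and 621 and 679 in the knockouts. Its level was 51.0 ± 4.98 normalized CPM in the controls and 24.98 ± 1.84 in the knockouts, a log2 fold change of -1.03 ± 0.16 (edgeR adjusted p = 0.00561). The reduction missed the threshold without control replicate 3, at a log2 fold change of -0.92 and an edgeR adjusted p of 0.0812; over all alternatives the adjusted p ran from 2.28e-16 to 0.0812. A knockout by small insertions or deletions can leave the transcript in place, and counts per gene do not show the edit. DNMT1 and RB1, chosen before the data were examined, did not pass the test. DNMT1, the maintenance DNA methyltransferase, was at 383 ± 19.1 normalized CPM in the controls and 297 ± 74.1 in the knockouts (edgeR adjusted p = 0.191), and RB1, the retinoblastoma tumour suppressor, at 30.4 ± 2.59 and 40 ± 5.55 (edgeR adjusted p = 0.113).

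**Figure D1:**
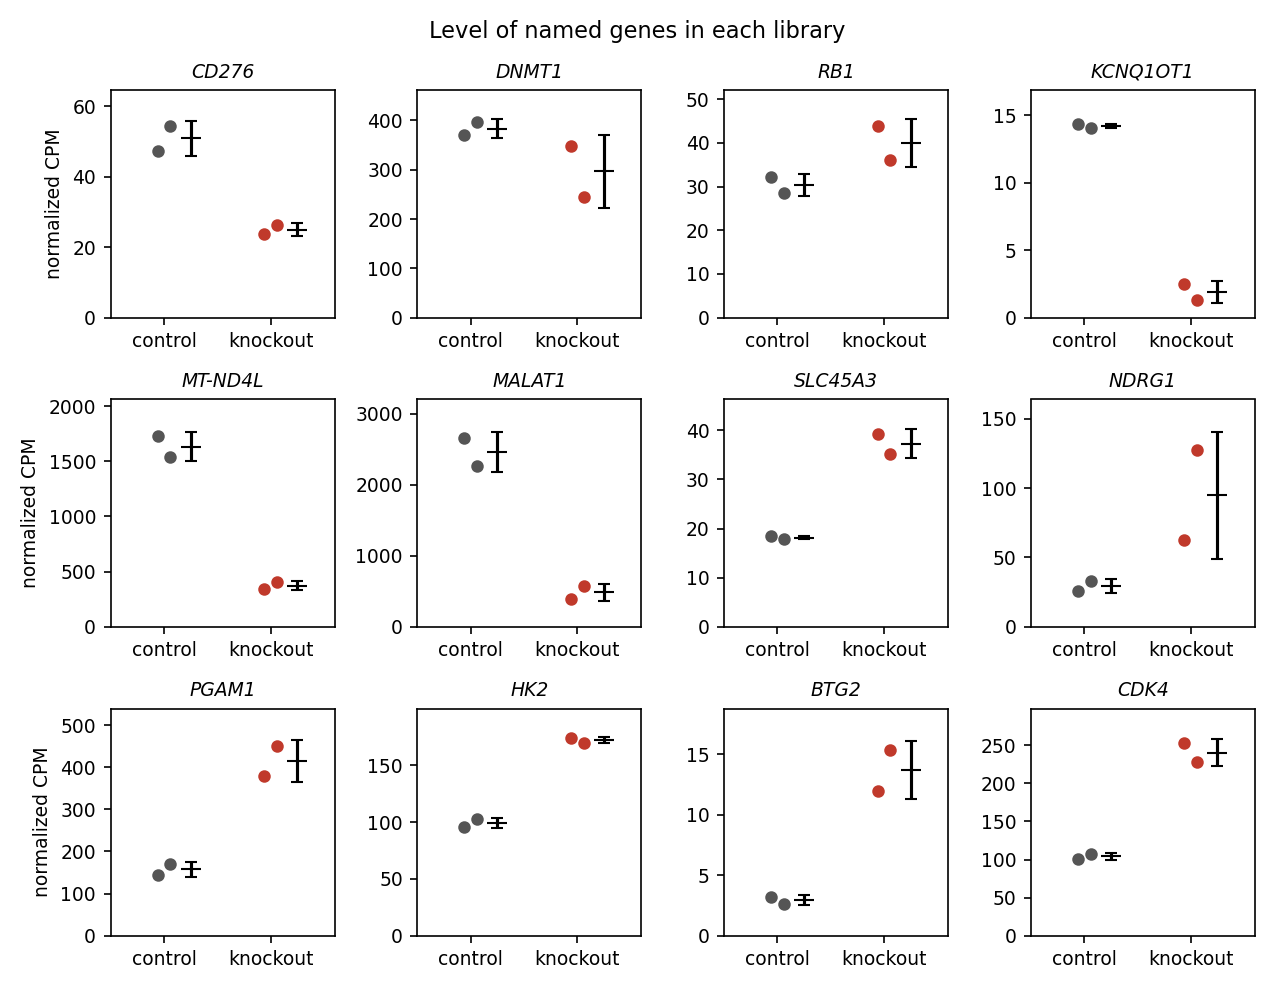
Normalized CPM (y axis) of named genes in each control (grey points) and knockout (red points) library, with the group mean and SD (n = 2) as a black bar beside them. Both knockout libraries lay below both controls for CD276, KCNQ1OT1, MT-ND4L and MALAT1 and above them for SLC45A3, NDRG1, PGAM1, HK2, BTG2 and CDK4. DNMT1 lay below and RB1 above both controls in both knockouts too, but neither passed the test.

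A large part of the transcriptome differed between the knockout and control libraries. Of 18043 genes tested, 1780 rose and 2331 fell, and 1647 of the 4111 changed at least 2-fold, 443 higher and 1204 lower. BTG2, an antiproliferative gene induced by p53, rose from 2.93 ± 0.42 to 13.7 ± 2.40 normalized CPM (log2 fold change 2.22 ± 0.25). SUCLG2, a subunit of the GDP-forming succinyl-CoA ligase of the citric acid cycle, rose from 17.1 ± 3.48 to 60.4 ± 5.36 (1.82 ± 0.18), and RAB11FIP1, an effector of RAB11 in endosome recycling, from 3.88 ± 0.73 to 14.8 ± 5.60 (1.94 ± 0.30). KCNQ1OT1, a long non-coding RNA of the imprinted KCNQ1 domain, fell from 14.2 ± 0.17 to 1.90 ± 0.82 normalized CPM (log2 fold change -2.90 ± 0.30), and CRYGS, a crystallin gene, from 7.57 ± 1.28 to 1.04 ± 0.17 (-2.86 ± 0.31). The edgeR adjusted p of these 5 genes was 0.00287, 0.00231, 0.00618, 0.00284 and 0.00284 in that order. RAB11FIP1 shares 24.8% of its exonic bases with a gene on the opposite strand and CRYGS 14.5% with a gene on the same strand, so part of their counts may belong to those genes.

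Most of the other genes with the largest changes also share sequence or annotated exons with neighbours or copies, so their counts are uncertain too. Among those that rose, SRXN1, which encodes sulfiredoxin (2.83 ± 0.46), TXNDC5, an endoplasmic reticulum disulfide isomerase (2.81 ± 0.36), CYP51A1, the lanosterol demethylase of cholesterol synthesis (2.12 ± 0.33), and COMMD7 (1.89 ± 0.21) shared 85.0%, 60.6%, 79.4% and 27.2% of their exonic bases with another gene on the same strand. ARL2BP, which binds the GTPase ARL2 (1.82 ± 0.34), shared 84.5% with genes on the opposite strand, and the strand setting of the counting is not given in the sources used here. NOMO3 (1.91 ± 0.42) has near-identical paralogs and TCAF1P1 (1.80 ± 0.51) is a pseudogene. Among those that fell, OR8B7P (-5.13 ± 0.47), FAR2P2 (-3.14 ± 0.29) and FAR2P3 (-2.87 ± 0.24) are pseudogenes. MTATP6P1 (-3.42 ± 0.32) is a nuclear copy of mitochondrial sequence, and NPIPB5 (-2.72 ± 0.22) belongs to a segmentally duplicated family. The remaining members of the 10 were the mitochondrial tRNA genes MT-TG (-3.12 ± 0.53), MT-TL2 (-3.05 ± 0.44) and MT-TH (-2.995 ± 0.37), which share no annotated exon. They are only 68, 71 and 69 bases long, so their reads may include neighbouring mitochondrial transcripts.

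**Figure D2:**
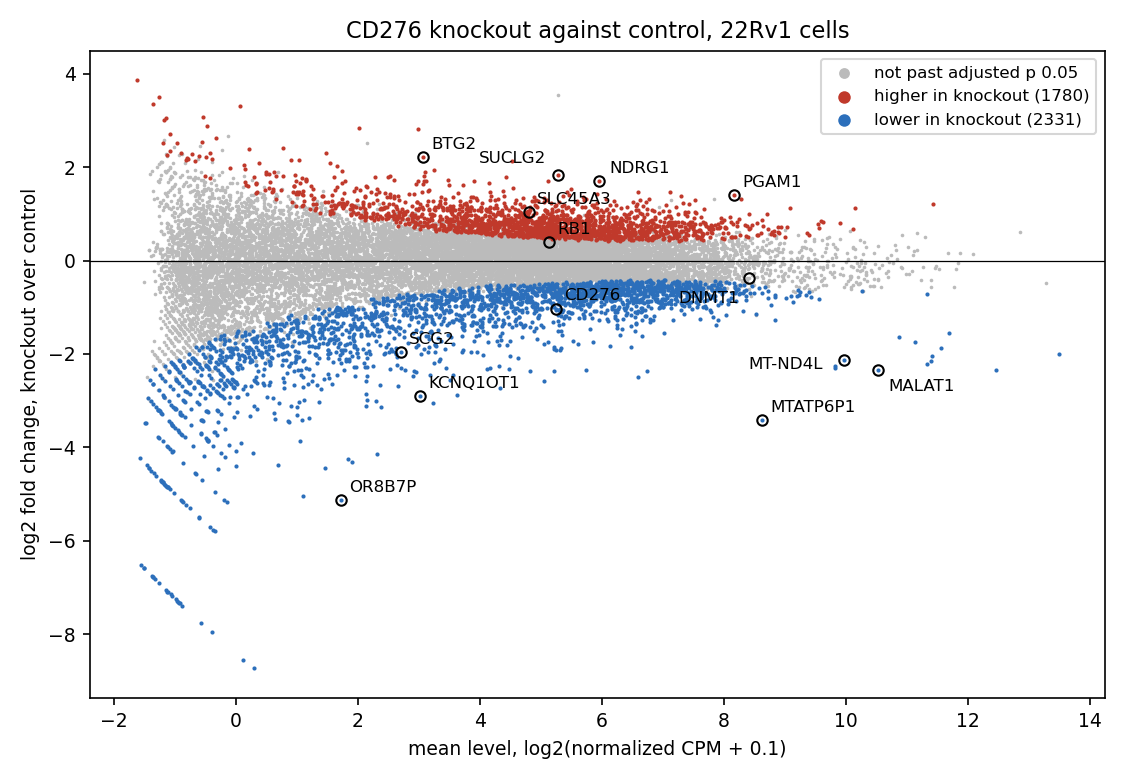
Log2 fold change of knockout over control (y axis) against mean level as log2 of normalized CPM plus 0.1 (x axis) for the 18043 genes tested; each point is a gene, grey where edgeR's adjusted p was 0.05 or more, red where it rose (1780) and blue where it fell (2331). Named genes are circled; MALAT1 and MT-ND4L stand out among abundant genes that fell.

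All 4111 changed genes had both knockout libraries on the same side of both controls. With 2 libraries per group, a gene whose groups overlap can hardly pass the test, so this separation adds no support to the calls. It held for 11888 of the 18043 genes tested (65.9%), where chance gives 33.3% for a single gene. Genes share the same libraries, so any difference between the groups of libraries moves many of them together. Scaling by library totals alone shifted the median log2 fold change of all genes by 0.11 and gave 2337 higher and 1784 lower. The count also depended on each library: it was 312 without control replicate 1, 599 without control replicate 3, 8713 without knockout replicate 1 and 9198 without knockout replicate 3, and 310, 597, 4063 and 4041 of the 4111 kept their call and direction. The controls were closer to each other (Pearson r = 0.990 of log2 CPM across genes, which are not independent replicates) than the knockouts were (r = 0.979), and r between groups was 0.953 to 0.962. The first principal component, with 70.8% of the variance, separated the groups, and the second, with 20.6%, separated the 2 knockout libraries from each other.

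Transcripts of the mitochondrial genome had the largest median fall of all gene lists fixed before the data were examined. Of the 13 protein-coding mitochondrial genes tested, 12 fell and 0 rose, and 13 fell when adjusted over the list alone, with a median log2 fold change of -2.04. At an unadjusted p under 0.05 edgeR gave 0 higher and 13 lower, and DESeq2 called 0 higher and 12 lower. MT-CO1, a core subunit of cytochrome c oxidase chosen after its values were seen, fell from 18310 ± 280 to 4594 ± 173 normalized CPM (-1.99 ± 0.26), and MT-ND4L and MT-ND6, subunits of complex I, from 1632 ± 134 to 371 ± 42.2 (-2.14 ± 0.19) and from 1494 ± 82.1 to 312 ± 82.0 (-2.26 ± 0.22). MT-ATP8, a subunit of ATP synthase, fell by 2.30 ± 0.19 on the log2 scale. All mitochondrial genes together took 5.84% and 6.15% of the counts of the 2 controls and 1.46% and 1.78% of those of the 2 knockouts. In limma's camera test with a preset correlation the list had an adjusted p of 2.95e-08 over 36 lists; the adjusted p was 0.954 with an estimated correlation, which gave that value or more for every list. The nuclear genes of oxidative phosphorylation did not move as a list (camera adjusted p = 0.493): 5 of 40 rose, 7 fell and 28 were not called, or 6 higher and 11 lower when adjusted over the list alone and 6 and 5 when scaled by library totals. Their median relative to the controls was -0.45 in knockout replicate 1 and -0.08 in knockout replicate 3. NDUFB5 (0.99 ± 0.14) and SDHC (0.83 ± 0.14) rose and NDUFA1 (-1.05 ± 0.21) fell. NDUFA1 shares 44.5% of its exonic bases with a gene on the opposite strand, so part of its counts may belong to that gene.

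Non-coding genes and pseudogenes fell far more often than they rose. Among 13775 nuclear protein-coding genes, 1685 rose and 1540 fell, with a median log2 fold change of 0.06. Their balance depended on the scaling: 1506 rose and 1627 fell under upper quartile scaling, and 2194 and 1105 under library totals alone. Of 887 lincRNA genes 19 rose and 124 fell, of 1234 antisense genes 30 rose and 188 fell, and of 177 sense intronic genes 0 rose and 56 fell, with medians of -0.23, -0.30 and -0.98. Sense intronic genes that rose numbered 1 at an unadjusted p under 0.05 in edgeR and 0 by DESeq2. Scaled by library totals alone, 29, 41 and 0 genes of these 3 types rose and 100, 159 and 50 fell. Offsets for GC content and transcript length left 41.9% (26.9 to 52.5 over resampled genes) of the median of the 3 types together. Of 533 processed and 161 unprocessed pseudogenes, 15 and 4 rose and 104 and 44 fell. The unprocessed pseudogenes include MTATP6P1, a nuclear copy of mitochondrial sequence, so part of their fall may repeat that of mitochondrial transcripts. MALAT1, an abundant nuclear long non-coding RNA, chosen after its values were seen, fell from 2458 ± 281 to 482 ± 125 normalized CPM (-2.35 ± 0.24, edgeR adjusted p = 0.00234). Its share was 0.255% and 0.218% of counts in the controls and 0.0423% and 0.0571% in the knockouts. Counts of antisense and intronic genes include reads of the gene they overlap where strand was not used.

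**Figure D3:**
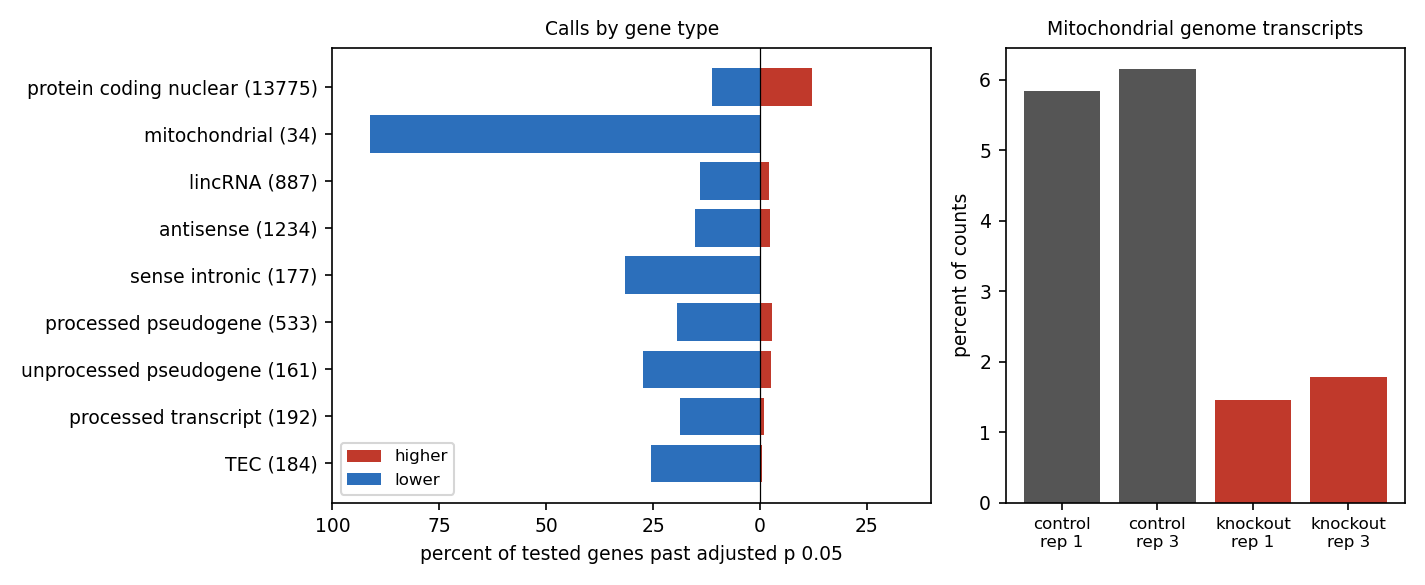
Left, percent of tested genes of each annotated type (number tested in brackets) that rose (red, to the right) or fell (blue, to the left) at edgeR's adjusted p under 0.05. Right, percent of all counts in mitochondrial genes in each library, 5.84 and 6.15 in the controls and 1.46 and 1.78 in the knockouts.

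Hypoxia and glycolysis genes and p53 targets passed camera with a preset correlation, but neither list passed with an estimated correlation (adjusted p = 0.954 for both) or with fry (adjusted p = 0.461 and 0.349). None of the 36 lists passed either of these tests, mitochondrial transcripts included, so they do not tell the lists apart. Of 33 hypoxia and glycolysis genes 11 rose, 0 fell and 22 were not called, with 12 higher and 0 lower when adjusted over the list alone and a median log2 fold change of 0.40 (camera adjusted p = 0.00144). No member fell at an unadjusted p under 0.05 in edgeR (0) or by DESeq2 (0, with 13 higher). PGAM1, a glycolytic mutase, rose from 158 ± 18.02 to 415 ± 50.7 normalized CPM (1.39 ± 0.17), HK2, a hexokinase, from 99.2 ± 4.52 to 172 ± 2.69 (0.79 ± 0.13), and MXI1, a MYC antagonist, from 26.2 ± 2.46 to 55.0 ± 9.22 (1.07 ± 0.17). Of 30 p53 targets 8 rose, 1 fell and 21 were not called, with 10 and 1 when adjusted over the list alone and a median of 0.41 (camera adjusted p = 0.00455). Besides BTG2, the ribonucleotide reductase subunit RRM2B (1.24 ± 0.16) and the cyclin CCNG1 (0.85 ± 0.17) rose. The median of the hypoxia and p53 lists, as log2 fold change relative to the mean of the controls, was 0.08 and 0.19 in knockout replicate 1 and 0.73 and 0.50 in knockout replicate 3. Without knockout replicate 3 neither list passed, with medians of 0.15 and 0.26 and camera adjusted p of 0.134 and 0.0964; without knockout replicate 1 the hypoxia median was 0.74 (camera adjusted p = 6.79e-08).

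The median of the immediate early genes, which cells induce within minutes of growth factors or stress, lay on opposite sides of the controls in the 2 knockout libraries. Of 25 tested 2 rose, 0 fell and 23 were not called (1 and 0 when adjusted over the list alone), and the list did not pass (camera adjusted p = 0.193), although it did with GC and length offsets (0.0358, upward; 0.982 with an estimated correlation). Of its genes, 7 rose and 0 fell at an unadjusted p under 0.05 in edgeR, and 3 and 0 by DESeq2. Its median log2 fold change relative to the controls was -0.40 in knockout replicate 1 and 1.10 in knockout replicate 3. FOS, a subunit of AP-1 chosen after its values were seen, was at 76.3 and 76.0 normalized CPM in the controls, 7.02 in knockout replicate 1 and 330 in knockout replicate 3. The 2 members that rose, BTG2 and EGR2, lay above both controls in both knockout libraries. EGR2 rose (3.31 ± 0.95) on counts of only 3 and 4 in the controls and 12 and 77 in the knockouts. EGR3 was not called, with 24 and 29 counts in the controls and 36 and 347 in the knockouts.

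**Figure D4:**
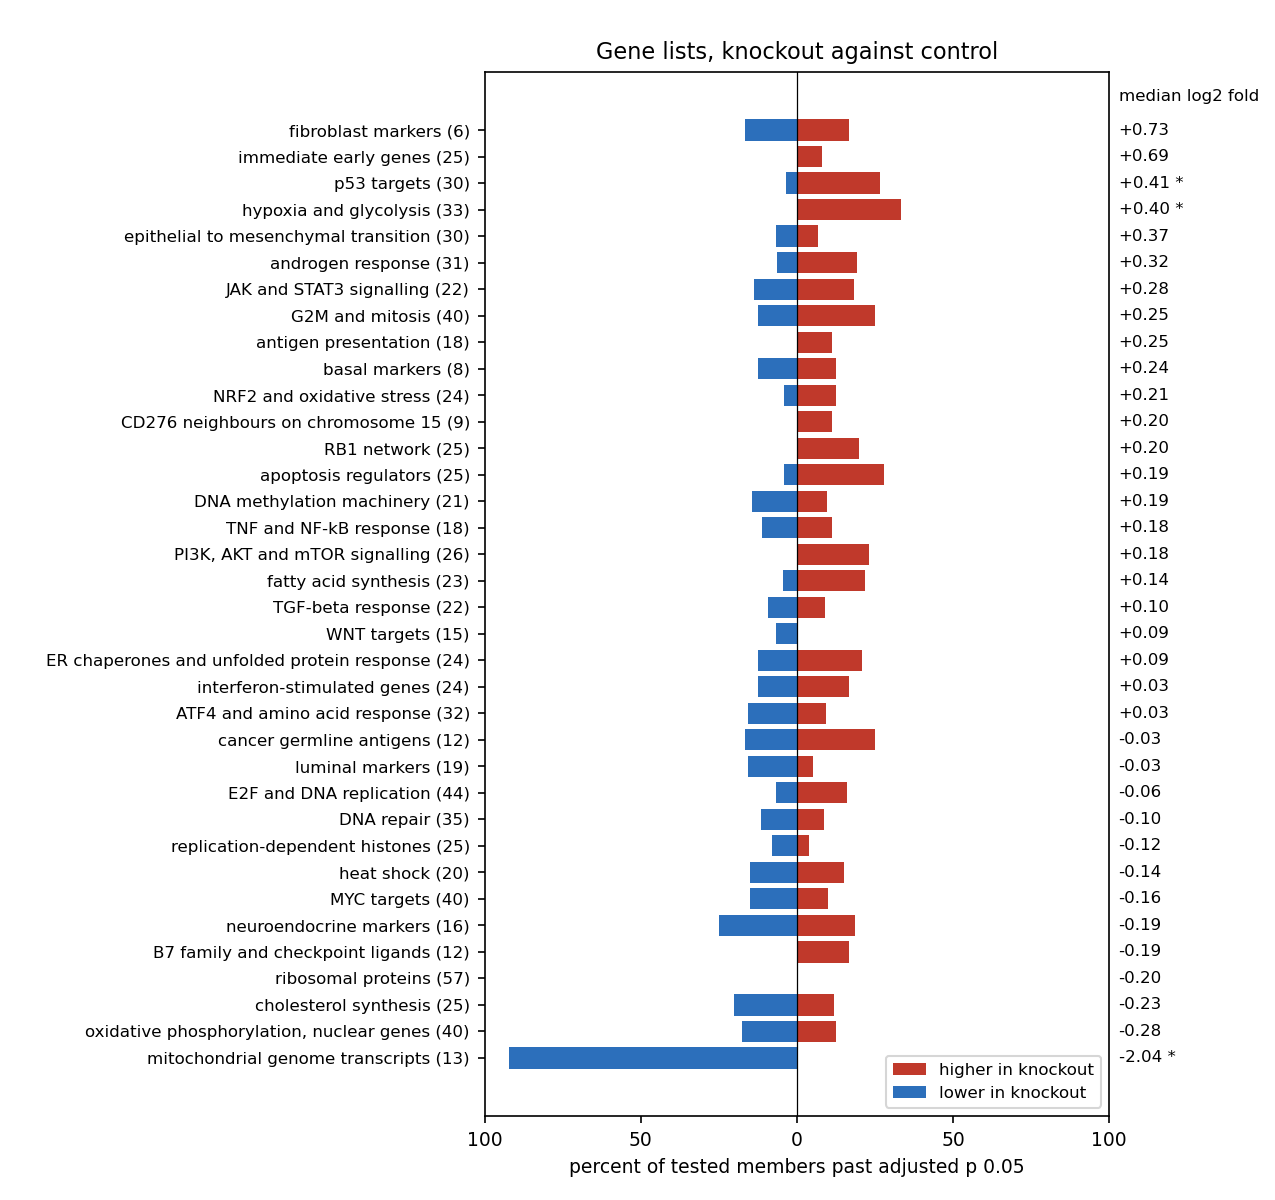
Percent of tested members of each gene list (number tested in brackets) that rose (red, to the right) or fell (blue, to the left) at edgeR's adjusted p under 0.05, ordered by the list's median log2 fold change, printed at the right. An asterisk marks the 3 lists that passed camera with a preset correlation: mitochondrial genome transcripts, hypoxia and glycolysis, and p53 targets.

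Lineage markers of the prostate moved in both directions, and none of these lists passed camera. Of 31 androgen response genes 6 rose, 2 fell and 23 were not called (7 and 2 when adjusted over the list alone; camera adjusted p = 0.141). SLC45A3, which encodes prostein, rose from 18.2 ± 0.38 to 37.3 ± 2.92 normalized CPM (1.04 ± 0.16) and NDRG1, also a hypoxia gene, from 29.2 ± 4.87 to 94.8 ± 45.7 (1.70 ± 0.30), while NNMT, nicotinamide N-methyltransferase, fell from 3.70 ± 0.99 to 0.461 ± 0.049 (-2.99 ± 0.41). KLK3, which encodes prostate-specific antigen and was chosen after its values were seen, was at 33.8 ± 2.65 and 34.1 ± 3.05. Of 16 neuroendocrine markers 3 rose, 4 fell and 9 were not called, with the same counts adjusted over the list alone: the secretory granule gene SCG2 (-1.97 ± 0.26) and the transcription factor ONECUT2 (-0.89 ± 0.18) fell and the synaptotagmin SYT4 (0.83 ± 0.15) rose. Scaled by library totals the androgen response, neuroendocrine and luminal counts were 9 and 2, 3 and 3, and 2 and 3. Of 19 luminal markers 1 rose, 3 fell and 15 were not called, including lower MUC1 (-1.82 ± 0.40), AGR2 (-0.57 ± 0.13) and the keratin KRT18 (-0.68 ± 0.19), and adjusted over the list alone the counts were 1 and 3. Of 8 basal markers ITGA6 (1.32 ± 0.39) rose and the hyaluronan receptor CD44 (-1.30 ± 0.24) fell, or 2 and 1 when adjusted over the list alone, the second gene to rise there being NGFR (1.52 ± 0.52). NGFR shares 27.1% of its exonic bases with genes on the opposite strand.

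The changed genes of the RB1 network all rose, while those of DNA methylation moved in both directions. Of 25 RB1 network genes 5 rose, 0 fell and 20 were not called (4 and 0 when adjusted over the list alone); 2 were lower at an unadjusted p under 0.05 in edgeR and 0 by DESeq2. CDK4, a kinase that phosphorylates RB1, rose from 104 ± 5.02 to 240.5 ± 17.9 normalized CPM (1.21 ± 0.14), CDK6 from 20.2 ± 0.16 to 37.0 ± 3.896 (0.88 ± 0.16) and CDKN2C, an inhibitor of both, from 44.9 ± 2.54 to 71.1 ± 7.34 (0.66 ± 0.14). CDK4 shares 43.2% of its exonic bases with a gene on the opposite strand, so part of its counts may belong to that gene. Of 21 genes of DNA methylation 2 rose, 3 fell and 16 were not called, with the same counts adjusted over the list alone: HELLS, a remodeller needed for DNA methylation (-0.81 ± 0.15), and MBD3 (-0.70 ± 0.15) fell and IDH1, an isocitrate dehydrogenase (0.68 ± 0.15), rose. Of 12 cancer germline antigens 3 rose and 2 fell, also when adjusted over the list alone, with higher MAGEA4 (0.59 ± 0.14) and lower SYCP3 (-1.86 ± 0.37) and SSX2 (-1.46 ± 0.31). MAGEA and SSX genes have close paralogs whose reads the counting could split. The camera adjusted p of these 3 lists was 0.290, 0.827 and 0.858.

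Genes of the immune response did not move as lists. Of 24 interferon-stimulated genes 4 rose and 3 fell, with the same counts adjusted over the list alone: USP18, a protease that removes ISG15, rose from 8.003 ± 2.06 to 17.04 ± 2.54 normalized CPM (1.09 ± 0.23), while the ubiquitin-like ISG15 fell from 209 ± 19.8 to 117 ± 25.9 (-0.84 ± 0.18). Of 18 antigen presentation genes PDIA3 (0.87 ± 0.16) and the peptide transporter TAP1 (0.97 ± 0.19) rose and 0 fell, and of 12 genes of the B7 family and checkpoint ligands CD47 (0.78 ± 0.15) and NCR3LG1, the ligand of NKp30 (1.24 ± 0.36), rose and 0 fell; both counts were the same adjusted over the list alone, and 0 members of either fell at an unadjusted p under 0.05 in edgeR or by DESeq2. Of 18 genes of the TNF and NF-kB response 2 rose and 2 fell, also over the list alone, with higher SOD2 (0.77 ± 0.13) and SDC4 (0.65 ± 0.17) and lower CEBPB (-0.74 ± 0.18). The camera adjusted p of these 4 lists was 0.607, 0.485, 0.791 and 0.551.

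Cell cycle and DNA repair genes changed in both directions. Of 40 G2M and mitosis genes 10 rose and 5 fell (13 and 8 when adjusted over the list alone). The spindle checkpoint gene MAD2L1 (1.22 ± 0.14), CKS2 (1.42 ± 0.16) and DLGAP5 (1.30 ± 0.17) rose. Of 44 E2F and DNA replication genes 7 rose and 3 fell (9 and 5 over the list alone), with higher MCM6, a subunit of the replicative helicase (1.31 ± 0.19), and RPA2 (0.68 ± 0.14) and lower CLSPN (-0.86 ± 0.20). Of 40 MYC targets 4 rose and 6 fell (6 and 12 over the list alone), with higher transferrin receptor TFRC (1.03 ± 0.16) and chaperonin HSPD1 (1.13 ± 0.19) and lower NOP2 (-0.87 ± 0.15), which shares 54.4% of its exonic bases with another gene. Of 35 DNA repair genes 3 rose and 4 fell, also over the list alone, with higher PARP1 (0.84 ± 0.18) and lower MRE11 (-1.16 ± 0.21) and XRCC1 (-0.71 ± 0.13). Of 25 replication-dependent histone genes 1 rose and 2 fell, or 0 and 0 when adjusted over the list alone: HIST1H2AG (1.202 ± 0.28), HIST1H4C (-1.58 ± 0.45) and HIST1H4A (-2.38 ± 0.68), the last on 16, 10, 3 and 3 counts. Of 57 ribosomal protein genes 0 rose and 0 fell, also over the list alone; edgeR gave 2 higher and 4 lower at an unadjusted p under 0.05, and DESeq2 called 2 and 3. Their median relative to the controls was -0.49 in knockout replicate 1 and 0.04 in knockout replicate 3. Scaled by library totals, the higher and lower counts of these 6 lists were 13 and 2, 9 and 1, 6 and 3, 4 and 2, 3 and 2, and 2 and 0, so their balance depends on the scaling. Their camera adjusted p was 0.262, 0.892, 0.551, 0.791, 0.791 and 0.369; with GC and length offsets DNA repair passed downward (0.0306) and histones upward (0.0147), neither with an estimated correlation (0.982 for both). For the E2F, histone and cancer germline lists the median was negative although camera's direction was up.

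Of 25 cholesterol synthesis genes 3 rose and 5 fell (5 and 6 when adjusted over the list alone): besides CYP51A1, which rose, the decarboxylase MVD (-0.82 ± 0.13) and the isomerase EBP (-0.75 ± 0.14) fell. Of 23 fatty acid synthesis genes 5 rose and 1 fell, also over the list alone, with higher ELOVL5, a fatty acid elongase (1.18 ± 0.14), GPAM (1.43 ± 0.27) and ACSL1 (0.73 ± 0.14). Of 32 ATF4 and amino acid response genes 3 rose and 5 fell (4 and 6 over the list alone), with lower NUPR1 (-1.02 ± 0.14) and DDIT3, which encodes CHOP (-1.01 ± 0.16), and higher MTHFD2 of mitochondrial one-carbon metabolism (0.78 ± 0.15). Of 24 endoplasmic reticulum chaperones and unfolded protein response genes 5 rose and 3 fell (5 and 4 over the list alone), with higher PDIA6 (0.83 ± 0.16), the stress sensor ERN1 (0.99 ± 0.20) and DNAJB9 (0.81 ± 0.18). Of 20 heat shock genes 3 rose and 3 fell, also over the list alone. HSPA4L rose (0.73 ± 0.16), and HSPA1B, whose near-identical copy is HSPA1A, fell (-0.57 ± 0.14). HSPA1B also shares 36.5% of its exonic bases with another gene on the same strand. Of 24 NRF2 and oxidative stress genes 3 rose and 1 fell, also over the list alone, with higher ferritin heavy chain FTH1 (1.29 ± 0.19), which has many processed pseudogenes, and lower ABCC2 (-1.25 ± 0.20). Genes on the opposite strand share 62.4% of the exonic bases of FTH1, 33.2% of MTHFD2, 31.6% of DDIT3 and 25.2% of PDIA6. Part of their counts may belong to those genes. Scaled by library totals, the higher and lower counts of these 6 lists were 5 and 4, 5 and 1, 6 and 4, 5 and 0, 3 and 2, and 5 and 1, so the balance of several depends on the scaling. Their camera adjusted p was 0.791, 0.391, 0.892, 0.551, 0.791 and 0.463.

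Of 26 genes of PI3K, AKT and mTOR signalling 6 rose and 0 fell, also when adjusted over the list alone, among them the regulatory subunit PIK3R1 (0.99 ± 0.19), FOXO3 (0.73 ± 0.16) and IRS1 (0.74 ± 0.18); 3 were lower at an unadjusted p under 0.05 in edgeR and 0 by DESeq2. Of 25 apoptosis regulators 7 rose and 1 fell, also over the list alone, with higher APAF1 of the apoptosome (0.94 ± 0.16), DIABLO (0.81 ± 0.16) and the antiapoptotic MCL1 (0.74 ± 0.14). Of 22 JAK and STAT3 signalling genes 4 rose and 3 fell (6 and 4 over the list alone), with higher STAT3 (0.61 ± 0.14) and STAT5A (1.10 ± 0.24). Of 30 genes of the epithelial to mesenchymal transition 2 rose and 2 fell (1 and 2 over the list alone), with higher integrin ITGB1 (1.003 ± 0.15) and lower TAGLN (-0.96 ± 0.18) and collagen COL1A1 (-1.001 ± 0.21). Of 22 TGF-beta response genes 2 rose and 2 fell, also over the list alone, with higher KLF10 (1.47 ± 0.17) and lower ID1 (-0.84 ± 0.16). Of 15 WNT targets DKK1, a secreted WNT antagonist, fell (-1.40 ± 0.19) and 0 rose, also over the list alone, with 3 higher at an unadjusted p under 0.05 in edgeR and 1 by DESeq2. Scaled by library totals, the higher and lower counts of these 6 lists were 6 and 0, 7 and 0, 6 and 1, 3 and 2, 4 and 2, and 2 and 1. Their camera adjusted p was 0.290, 0.193, 0.290, 0.290, 0.551 and 0.791.

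Of 9 tested genes near CD276 on chromosome 15, BBS4 rose (0.52 ± 0.15) and 0 fell, or 0 and 0 when adjusted over the list alone (camera adjusted p = 0.791); 2 were lower at an unadjusted p under 0.05 in edgeR and 0 by DESeq2. Markers of other cell types were scarce. Of 6 fibroblast markers tested LUM rose from 7.72 ± 1.57 to 13.9 ± 0.07 normalized CPM and COL1A1 fell from 48.1 ± 2.71 to 24.0 ± 7.26, with the same counts over the list alone (camera adjusted p = 0.290). Only 2 leukocyte and 2 endothelial markers passed the filter on low counts, 0 of them called over all genes by edgeR or by DESeq2. CD14, the leukocyte marker with an unadjusted p under 0.05 in edgeR, chosen after its values were seen, fell when adjusted over the list alone (-1.65 ± 0.57).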

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

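The protein-coding and GC offset alternatives were chosen only after the data were seen; all others were planned. With all 4 libraries, 3790 to 5353 genes were called over the other scalings, filters and tools, including 3926 by DESeq2 and 3998 by limma voom, against 4111. Leaving out 1 library moved the count to between 312 and 9198, and the genes changed at least 2-fold from 1647 to between 312 and 2628. It was 312 and 312 without control replicate 1, 599 and 594 without control replicate 3, 8713 and 2628 without knockout replicate 1, and 9198 and 2541 without knockout replicate 3: with a single control the spread comes from the knockouts, which differ more. An adjusted p under 0.01 left 1036 genes and a test against a 1.2-fold change 2517, and 858 protein-coding genes changed at least 2-fold when tested alone (fewer genes tested). CD276 was lower in every alternative and missed the threshold in 1, without control replicate 3 (-0.92, edgeR adjusted p = 0.0812); over the left-out libraries its log2 fold change ran from -1.13 to -0.92. The deviations of same-numbered libraries were hardly correlated (-0.0152). With 2 libraries per group this cannot tell whether the numbers mark a shared day or culture. With the replicate block edgeR called 4843 genes, and CD276 (-1.03) and the 3 lists kept their calls. Lists called were 3 with all genes, 7 without a filter and 6 with GC offsets (also immediate early genes and histones upward and DNA repair downward; the cause was not tested), 3 to 5 with a library left out, 5 being without knockout replicate 1. No list passed with an estimated correlation (0, with 0 at an unadjusted p under 0.05) or with fry, which tests for a shift one way (0, with 4 at an unadjusted p under 0.05, while fry's mixed p called 34 of 36). Over its alternatives the camera or fry adjusted p ran from 1.45e-11 to 0.954 for mitochondrial transcripts, from 6.79e-08 to 0.954 for hypoxia and glycolysis and from 0.000153 to 0.954 for p53 targets. Of 1779 alternatives over 120 named genes, 1593 kept direction and side of the threshold, 156 lost the call, 30 gained it and 0 reversed; of 109 called named genes 31, 47, 107 and 106 stayed called without control replicates 1 and 3 and knockout replicates 1 and 3. Of 572 over the lists, 553 kept both, 8 lost and 11 gained the call. Depth limited genes with few counts in the self-test, whose rates need not hold for the data. It recovered 62% of 2-fold changes. By level these were 13 of 67 for genes at 1.01 to 9.18 CPM and 61 of 67 for those at 39.7 CPM or more.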

Other observations

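Chosen only after the results were seen were the 10 gene families, the genes named outside the rule, the density comparison for genomic DNA, the GC test of mitochondrial transcripts, the comparison with respiratory chain genes, the histone values with GC offsets, the count of calls in shifted windows, and the GC offset alternative.

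Part of the RAB family, small GTPases of membrane traffic, rose in the knockouts. Of 57 tested 19 rose, 0 fell and the rest were not called, with a median log2 fold change of 0.36, and the counts were 19, 17 and 24 higher and 0, 0 and 0 lower under RLE, upper quartile and library-total scaling. RAB14 rose from 36.5 ± 2.10 to 80.9 ± 15.3 normalized CPM (1.15 ± 0.17), RAB7A of late endosomes from 181 ± 13.3 to 332 ± 2.95 (0.87 ± 0.14) and RAB6A of the Golgi from 80.8 ± 11.3 to 153 ± 3.66 (0.92 ± 0.15). Among 10 families set against protein-coding genes, camera gave an adjusted p of 0.00300, and the adjusted p was 0.822 with an estimated correlation. No family passed with an estimated correlation. The families were chosen after the results were seen, and the camera adjusted p given here and below does not allow for that choice. Of 33 ubiquitin-conjugating enzymes of the UBE2 family 9 rose and 1 fell, including higher UBE2D2 (0.75 ± 0.15) and lower UBE2C (-0.69 ± 0.14). The family passed camera (adjusted p = 0.0380; 0.847 with an estimated correlation) but not with GC offsets (0.197).

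Zinc finger genes, mostly transcription factors with tandem zinc fingers, fell more often than they rose. Of 465 ZNF genes 18 rose and 78 fell (camera adjusted p = 0.0164; adjusted p = 0.876 with an estimated correlation), and under library-total scaling 25 rose and 49 fell. ZNF692 fell from 130 ± 6.99 to 56.3 ± 0.03 normalized CPM (-1.21 ± 0.13), ZNF700 from 51.5 ± 2.498 to 14.8 ± 4.30 (-1.80 ± 0.21) and ZNF292 from 59.6 ± 2.53 to 27.9 ± 0.08 (-1.09 ± 0.14). The other families did not pass camera, although with GC offsets SR splicing factors (adjusted p = 0.0116), HNRNP genes (0.0310) and dynein and kinesin genes (0.0310) passed downward, none of them with an estimated correlation (0.379, 0.661 and 0.379). Of 234 solute carriers 25 rose and 23 fell (37 and 18 under library-total scaling), of 191 TMEM genes 25 and 15 (31 and 12), of 78 mitochondrial ribosomal proteins 5 and 12 (10 and 11), of 37 proteasome subunits 2 and 5 (6 and 3), of 52 dynein and kinesin genes 2 and 6 (4 and 5), and of 23 HNRNP genes 1 and 1 (2 and 0), so most of these balances depend on the scaling. Of 12 SR splicing factors SRSF3 rose (0.74 ± 0.15) and SRSF4 (-0.83 ± 0.14) and SRSF11 (-1.05 ± 0.14) fell.

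The fall of non-coding transcripts may come from more nuclear or intron-containing RNA in the control libraries. Across 13775 protein-coding genes, the share of annotated exonic bases found only in retained-intron transcripts correlated with the log2 fold change (Spearman rho = -0.168, interval -0.184 to -0.152 over resampled genes, which are not independent; -0.155 given level, GC content and length). For genomic DNA, 494 olfactory receptor, taste receptor and keratin-associated genes, normally silent outside their own tissues, were summed. Their CPM in the lowest control was 1.43 times that of the highest knockout, between the bounds fixed beforehand, so this ratio alone cannot tell. They lay at 0.0184 CPM per kb in the controls, against a median loss of 1.63 CPM per kb (1.41 to 1.82) in the 368 non-coding genes that fell. That argues against genomic DNA for those 368 genes only, as they were picked by their fall. GC content and length stay open as a partial cause, since offsets for them left 41.9% of the non-coding median (26.9 to 52.5), and so does a difference in RNA without poly(A) tails, since the interval of the histone median, -0.12 (-0.28 to 0.66), spans the -0.16 needed and the knockout libraries differed (-0.44 in replicate 1 and 0.21 in replicate 3). With the offsets the histone list passed camera upward with a preset correlation (adjusted p = 0.0147) but not with an estimated one (adjusted p = 0.982). The interval of its median, 0.15 (-0.0725 to 0.938), still reached the -0.0674 then needed, so the histone genes do not decide about missing tails. The knockout itself stays open too, as the design cannot part it from a difference in how the groups' RNA was prepared.

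The fall of mitochondrial transcripts was not matched in size by the medians of the nuclear gene sets tested. Offsets for GC content and length left most of it. The median log2 fold change of 26 nuclear genes for mitochondrial transcription and RNA stability was 0.02 (0.0203, -0.216 to 0.218). Of them 3 rose, among them TFB2M (1.25 ± 0.20) and TFAM (0.70 ± 0.15), and 2 fell, SLIRP (-0.83 ± 0.19) and SUPV3L1 (-0.46 ± 0.14). A median over genes that moved both ways argues only against a shared fall and cannot exclude the fall of a single factor. The median of nuclear respiratory chain genes was -0.28 (-0.35 to -0.06), with -0.45 in knockout replicate 1 and -0.08 in knockout replicate 3. It was short of the -1.02 set as the bound for a shared fall. GC and length offsets left 81.3% of the fall (75.1 to 94.4), which argues against them as its whole cause. Leaving mitochondrial genes out moved the non-coding median slightly away from 0, from -0.3217 to -0.3255 (-1.17% toward 0). The scaling by trimmed mean of M-values already leaves out genes with extreme changes. A larger move was therefore unlikely, and the comparison decides little about the share of mitochondrial counts. A lower mitochondrial DNA copy number in the knockout cells or a difference in RNA preparation could each give this pattern, and neither was tested.

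The 4111 calls between 2 and 2 libraries may in part reflect copy number differences between cultures of this line. Of 1173 windows of 50 neighbouring genes 19.8% had a median outside the 99% range of shuffled windows (10.1% with GC offsets), but the window medians also followed GC content (Spearman rho = -0.737 across windows), so the 2 cannot be told apart. Of 3143 protein-coding calls, 30.4% lay in a window shifted the same way, so most lay outside windows past the 99% range. With only 19.8% of windows past it, a low share was likely, and no share for uncalled genes was taken. Whether copy number gave most calls thus stays undecided. GC content or length as the source of most calls is argued against, since 83.9% of 3225 protein-coding calls held with the same sign with offsets. An effect of the knockout, of separate clones or of culture conditions stays open, as the labels do not say whether the knockout cells were a pool or a clone, and the 2 knockouts themselves differed, with FOS at 7.02 and 330 normalized CPM.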
